A study of Homo sapiens with 12 samples.

How the data were processed

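RNA was sequenced from 12 libraries of a co-culture of 2 human cell lines, Jurkat and Raji, 1 library for each of 4 antibody arms at each of 3 antibody doses. The molecule is labelled polyA RNA, while the extraction protocol in the labels describes total RNA, so the selection step is not settled by the sources used here. Nothing in the labels says that any library is a replicate of another, and each condition has 1 library. P-values therefore measure the spread between these libraries, which may be technical, and not the spread between repeated cultures.

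The authors deposited a table of raw read counts for 55782 gene symbols, with no line that names no gene. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and the genome build GRCh38 were used, named there without their order or settings. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Genes with near-identical copies, such as ribosomal protein pseudogenes, XCL1 and XCL2, the HLA genes, the NPIP family, TRBC1 and HSPA1A with HSPA1B, and genes with an antisense partner, are therefore uncertain. The deposited counts are not normalised. The deposited table also gives a length in base pairs for each gene symbol, per the file headers. The authors also deposited, for each of the 9 antibody-treated libraries, a table of log2 fold changes with their standard errors, and of p-values and adjusted p-values. Per the file headers each table compares 1 library with all 3 isotype libraries at once, and DESeq2 is named in the submitters' processing notes. Not used here were 4 count columns whose names match no sample in the labels, and 36 columns of per-sample values in the comparison tables.

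Counts were summed per library to give its depth, 23593973 to 36581754 counts. A count of 0 in a library allows up to 3 counts, which is 0.0838 to 0.129 CPM (counts scaled to library size) at these depths. Poisson intervals at 95% were computed for the genes that the cell lines are described as carrying, and for CD69, IL2 and IFNG. The 3 counts are a one-sided limit, so the upper ends of the two-sided intervals at 0 counts lie above it. Such intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

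Samples were grouped by the treatment label into isotype, anti-LAG3, anti-PD1 and the combination of anti-PD1 and anti-LAG3. Gene tests were made in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with arm as the group and a minimum count of 10, which left 15535 genes, and libraries were scaled by the trimmed mean of M values (TMM). Arm means were compared with edgeR's quasi-likelihood F test (robust) in a model of arm plus dose as a factor, with 6 residual degrees of freedom. In that model a dose response that differs between arms counts as spread. Dose trends were tested in a model with a slope on log10 dose for each arm, centred at 0.1 µg/ml, with 4 residual degrees of freedom, and the slope of the isotype series was subtracted. All 12 libraries shared 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 was called a change. Every adjusted p given for a gene below is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless the authors' deposited table is named, and a value after ± is a standard error unless SD is written. "Non-additive" refers to the combination minus anti-PD1 minus anti-LAG3 plus isotype on the log2 scale.

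The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The lists were TCR-induced early genes, cytokines and chemokines, NF-kB target genes, interferon response, IL-2 and STAT5 targets, checkpoint and costimulatory receptors and ligands, cytotoxic and death-ligand genes, apoptosis and growth arrest, cell cycle, glycolysis, cholesterol synthesis, amino acid and unfolded protein stress, heat shock, B cell activation, MHC class II and antigen presentation, MHC class I, mitochondrially encoded mRNAs, replication-dependent histone genes, ribosomal proteins, Jurkat T markers and Raji B markers. Some lists share members, for example EGR1 and EGR2 in the early genes and in B cell activation. These 21 lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. None of the 139 list calls made with the preset correlation held with an estimated correlation, and 16 of them held in fry, which does not compare a list with other genes.

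Genes were named by the following rule. LAG3, PDCD1, CD274, IL2, CD69 and IFNG were always reported. For each antibody arm against isotype, the 10 largest rises and the 10 largest falls in arm mean were taken among protein-coding genes that passed the test, had the same sign at all 3 doses and averaged at least 1 CPM, and for the other arm comparisons 5 and 5. Up to 4 members with the smallest p were taken for each list, and the 3 genes with the smallest p for each dose trend. Because the rule gave only 3 genes to each trend, the largest rises and falls in slope were added after the values were seen, and so were the comparisons of slopes between arms and the trend within the isotype arm. Gene positions, GC content and biotypes came from the GENCODE v29 annotation of GRCh38, in which 35914 symbols were found directly and 562 through an older symbol, while 19306 were not found. Of the genes tested, 89.7% had a GC value. A few named genes that the rule took are not reported here.

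The share of the cell lines was followed as the mean log2 CPM of the Jurkat T markers minus that of the Raji B markers in each library, with an exact two-sided permutation test between arms. Overlaps of arms compared with the same isotype libraries were set beside 20 simulations of unchanged arms and beside the overlap of independent lists. Those simulations drew each gene independently and held no GC or length bias of a library. They therefore cannot size what the shared controls explain.

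Alternatives were DESeq2 1.42.0 (Wald test), relative log expression and upper quartile scaling in edgeR, no filter on low counts, a mean of at least 5 CPM, no dose term, arm-specific dose slopes, doses 1 and 0.1 µg/ml only, the marker difference as a covariate, a fit without the robust option, only the arms compared, and leaving out each library in turn. Added after seeing the data were slopes tested against 0, and a correction for GC content and length. For it, a smooth of each library's log2 ratio on both (mgcv 1.9.3, genes with a mean log2 CPM over 3) entered the fit as an offset. Genes without a GC value were left uncorrected, and genes of lower expression took the smooth fitted on the others.

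The tests were checked on simulated counts for 15535 genes, of which 200 were changed. Each gene was drawn independently, with no structure shared by the genes of a library. The false calls below hold for such counts only. For anti-LAG3 against isotype, edgeR recovered 25.4% of changes of 0.25 log2, 62.1% of 0.5 and 84.8% of 1, with 15 false calls among 128. For the non-additive effect the shares were 9.52%, 46.3% and 73.4%, with 7 false calls among 91. For the dose trend of the combination they were 21.2%, 68.7% and 65.2% for slopes of those sizes, with 3 false calls among 106. With DESeq2 the shares were 26.2%, 66.7% and 74.2% for anti-LAG3 against isotype, with 7 false calls among 117, and 24.2%, 59.7% and 60.6% for the trend, with 4 among 100. With a simulated GC bias and no effect, anti-LAG3 against isotype gave 3450 calls, and 2 after the correction. That bias was a straight line in GC content, steeper than that of any library here. Since GC content is a term of the correction, this shows only that such a bias is removed. The list test called the 1 list that was shifted and 0 of the 20 others.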

Results

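RNA was sequenced from co-cultures of Jurkat, a human T cell leukaemia line described in the labels as carrying LAG3 and PD1, and Raji, a human Burkitt lymphoma B cell line described as carrying PDL1. LAG3 and PD1 are inhibitory receptors of T cells, and PDL1 is a ligand of PD1. The Raji cells were loaded with staphylococcal enterotoxin D, a superantigen that links MHC class II to the T cell receptor (TCR), at 100 ng/ml, and the co-culture lasted 24 h. It was made with an isotype control antibody, with anti-LAG3 plus isotype, with anti-PD1 plus isotype, or with anti-PD1 plus anti-LAG3, called the combination here. Each arm was run at 1, 0.1 and 0.01 µg/ml of each antibody, with 1 library per condition and no replicate of any condition, so the 3 doses of an arm were its 3 libraries when arms were compared. RNA of both lines was read together, and no value can be assigned to 1 line beyond what is known of the gene.

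The isotype libraries held 36581754, 26457020 and 27313108 counts at 1, 0.1 and 0.01 µg/ml. The anti-LAG3 libraries held 31651624, 25187375 and 26261483 counts, and the anti-PD1 libraries 28361652, 24357959 and 23593973. The combination libraries held 25808464, 26980628 and 28709956 counts. Of 55782 gene symbols, 19441 had no count in any library and 15535 were tested.

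The genes that the cell lines are described as carrying were looked at first. PDCD1, which encodes PD1 (GRCh38 chromosome 2, 241849881 to 241858908, minus strand), was counted in all 12 libraries at 179 to 228 CPM. CD274, which encodes PDL1 (chromosome 9, 5450503 to 5470566, plus strand), was counted at 81.1 to 97.8 CPM. LAG3 (chromosome 12, 6772512 to 6778455, plus strand) had 0 to 2 counts in each library, with 0 in all 3 anti-LAG3 libraries. Its highest level was 0.0706 CPM, and the 95% Poisson intervals reached up to 0.255 CPM, so any difference in LAG3 RNA between arms was not detectable from these counts. PDCD1 had a slope of -0.16 ± 0.05 (SE) log2 per 10-fold dose in the combination against isotype (adjusted p = 0.0797), and CD274 one of 0.14 ± 0.05 (adjusted p = 0.140). PDCD1 was higher in the anti-LAG3 than the isotype arm, by 0.20 ± 0.05 log2 (adjusted p = 0.0254), but by 0.01 after the correction for GC content and length (adjusted p = 0.907). IL2 and IFNG, cytokine genes of activated T cells, had 0 to 4 counts per library, with the 4 counts of each in the combination at 1 µg/ml, and were not tested.

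The balance of the lines was followed by markers fixed beforehand, 24 of Jurkat T cells and 28 of Raji B cells. The mean log2 CPM of the T markers minus that of the B markers was -1.43 ± 0.05 (SD, n = 3) in the anti-LAG3 libraries and -1.63 ± 0.03 in the isotype libraries. The difference of 0.195 had an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow, and 0.308 after adjustment over the 7 arm comparisons. Anti-PD1 differed from isotype by 0.0426 (exact permutation p = 0.4) and the combination by 0.0196 (exact permutation p = 0.8). The last was -0.0137 by the median of markers (exact permutation p = 0.8) and 0.0478 with markers of at least 10 CPM (exact permutation p = 0.1). The combination differed from anti-LAG3 by -0.176 (exact permutation p = 0.1, and 0.308 after adjustment). Within the arms this difference had slopes of -0.0223 per 10-fold dose in isotype, 0.0355 in anti-LAG3, 0.0652 in anti-PD1 and -0.0872 in the combination.

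The first question was which genes followed the dose of the antibodies in the co-culture. With the combination, some of the genes that the T cell receptor switches on early rose with dose. CD69, an early activation antigen of lymphocytes (chromosome 12, 9752486 to 9760901, minus strand), stood at 52.2, 27.3 and 13.6 CPM at 1, 0.1 and 0.01 µg/ml, against 11.2, 13.5 and 12.2 CPM with isotype. EGR1, a zinc finger transcription factor of the immediate early response (chromosome 5, 138465490 to 138469315, plus strand), stood at 82.5, 41.2 and 19.7 CPM against 18.3, 16.9 and 18.6 CPM. ADA, adenosine deaminase, which breaks down adenosine (chromosome 20, 44619522 to 44652233, minus strand), went the other way, at 117, 195 and 310 CPM against 286, 253 and 252 CPM. TRAC, the constant region of the TCR alpha chain (chromosome 14, 22547506 to 22552154, plus strand), stood at 284, 167 and 108 CPM against 119, 102 and 102 CPM.

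Against the slope of the isotype series, 719 genes changed with the dose of the combination, 284 upward and 435 downward, by a median of 0.31 log2 per 10-fold dose. The 3 genes with the smallest p were ADA, with a slope of -0.80 ± 0.05 (SE; adjusted p = 3.95e-11), CASC15, a long intergenic RNA, with 0.86 ± 0.06 (adjusted p = 1.55e-09), and EGR1, with 1.04 ± 0.08 (adjusted p = 3.59e-09). CD69 rose by 1.03 ± 0.09 (adjusted p = 3.75e-08) and TRAC by 0.58 ± 0.06 (adjusted p = 3.26e-07). The largest slopes, chosen after the values were seen, included NR4A3, a nuclear receptor induced by antigen stimulation, with 2.26 ± 0.31 (adjusted p = 0.00168), and CRTAM, an adhesion molecule of activated T cells, with 2.75 ± 0.34 (adjusted p = 1.15e-05). MYO7B, an unconventional myosin, fell by 0.96 ± 0.06 (adjusted p = 3.75e-08), and DNTT, the terminal transferase of V(D)J recombination, by 0.91 ± 0.12 (adjusted p = 2.50e-05). The count rested on single libraries: it was 34 without isotype at 1 µg/ml, 302 without isotype at 0.01 µg/ml, 239 without the combination at 1 µg/ml and 101 without the combination at 0.01 µg/ml. It was also 290 with DESeq2, and 119 with the T minus B marker difference as a covariate, 62 upward and 57 downward.

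The TCR-induced early genes as a list rose with the dose of the combination, with 17 of 42 measured members up and 3 down, and 20 up and 4 down adjusted over the list alone (adjusted p of the list = 1.57e-06, and 0.0840 with an estimated correlation). EGR3 rose by 1.65 ± 0.19 log2 per 10-fold dose (adjusted p = 3.92e-06), EGR2, of the same family, by 1.13 ± 0.21 (adjusted p = 0.00132), and DUSP2, a phosphatase of MAP kinases, by 0.55 ± 0.06 (adjusted p = 1.06e-06). IL2RA, the alpha chain of the interleukin-2 receptor, rose by 1.58 ± 0.24 (adjusted p = 2.01e-04), a call that ended without isotype at 1 µg/ml (adjusted p = 0.379). Of 22 cytokines and chemokines 3 rose and none fell, and 3 rose and 1 fell adjusted over the list alone (list adjusted p = 0.192). XCL1, a chemokine of activated T cells (chromosome 1, 168576473 to 168582077, plus strand), had 15.0, 0.777 and 0.104 CPM with the combination and 0 to 2 counts in each isotype library (adjusted p = 0.0185). Its near-identical neighbour XCL2 had 6.85, 0.814 and 0 CPM (adjusted p = 0.00108), and IL16 rose by 0.24 (adjusted p = 0.0252). Of 33 NF-kB target genes 6 rose, and 9 adjusted over the list alone (list adjusted p = 7.55e-05, and 0.0840 with an estimated correlation). Among them were TNFAIP3, a feedback inhibitor of NF-kB, by 0.22, and NFKB2, a subunit, by 0.21.

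Of 28 checkpoint and costimulatory genes 5 rose with the combination dose, and 9 rose and 1 fell adjusted over the list alone (list adjusted p = 0.0188, and 0.195 with an estimated correlation). ICOS, a costimulatory receptor, rose by 1.59 ± 0.31 log2 per 10-fold dose, CD40LG, the ligand of CD40, by 1.81 ± 0.43, CD226 by 0.76 and CD28 by 0.53. MHC class I genes rose, with 4 of 13 up and 6 adjusted over the list alone (list adjusted p = 7.55e-05, and 0.0840 with an estimated correlation), among them HLA-C by 0.24. MHC class II genes had 0 of 17 called, and 3 up and 2 down adjusted over the list alone (list adjusted p = 0.171). Of 31 B cell activation genes 4 rose, also adjusted over the list alone (list adjusted p = 0.162). The interferon response list had 3 of 50 up and 2 down, and 5 up and 3 down adjusted over the list alone (list adjusted p = 0.152), with GBP2, a guanylate-binding protein, up by 2.28 and LAMP3 at -0.57. Of 12 cytotoxic and death-ligand genes 2 rose, and 2 rose and 1 fell adjusted over the list alone, with GZMB, granzyme B, at 1.54 (list adjusted p = 0.638; its median was -0.05 and its mean 0.10). IL-2 and STAT5 targets had 2 of 19 up and 3 down, and 4 up and 5 down adjusted over the list alone (list adjusted p = 0.850; the median of 0.02 and mean of 0.06 were positive while the test pointed down).

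Of the growth and metabolism lists, cell cycle fell with the combination dose, with 0 of 49 up and 2 down, and 5 down adjusted over the list alone (list adjusted p = 0.00289, and 0.339 with an estimated correlation), where CCND3, a D-type cyclin, fell by 0.16. Replication-dependent histone genes fell, with 2 of 23 down and 4 adjusted over the list alone (list adjusted p = 6.58e-06, and 0.235 with an estimated correlation), such as HIST1H4C by -0.52. Cholesterol synthesis rose, with 4 of 27 up and 5 adjusted over the list alone (list adjusted p = 0.00657, and 0.235 with an estimated correlation). HMGCS1, a synthase of the pathway, rose by 0.25. The apoptosis and growth arrest list rose, with 1 of 25 up and 1 down, and 4 up and 1 down adjusted over the list alone (list adjusted p = 0.0260, and 0.198 with an estimated correlation); PMAIP1, which promotes apoptosis, was up by 0.19, and BID, also pro-apoptotic, changed by -0.22. Glycolysis had 1 of 25 up, PFKM at 0.23, and 1 up and 1 down adjusted over the list alone (list adjusted p = 0.850; its median was -0.01 while the test pointed up). Amino acid and unfolded protein stress had 2 of 30 up and 1 down, also adjusted over the list alone (list adjusted p = 0.0945), and heat shock had 1 of 12 down, also adjusted over the list alone, HSPB1 at -0.67 (list adjusted p = 0.152).

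Ribosomal proteins fell with the combination dose, with 3 of 53 up and 11 down, and 7 up and 17 down adjusted over the list alone (list adjusted p = 0.0498, and 0.794 with an estimated correlation). RPL28 changed by -0.30 and RPL34 by 0.28. Without isotype at 1 µg/ml this list pointed up, and without the combination at 0.01 µg/ml so did the mitochondrial and Jurkat T lists that follow. Mitochondrially encoded mRNAs fell, with 1 of 13 down, also adjusted over the list alone (list adjusted p = 0.0260, and 0.637 with an estimated correlation). That member was MT-ND4L, at -0.24. The mitochondrial list also pointed up with the T minus B marker difference as a covariate. The Jurkat T markers fell as a list while its members went both ways, with 4 of 24 up and 6 down, and 4 up and 9 down adjusted over the list alone (list adjusted p = 0.0498, and 0.498 with an estimated correlation). TRAC rose by 0.58, while CD3E and CD3G, chains of the TCR complex, changed by -0.30 and -0.28, and BCL11B, a T lineage transcription factor, by -0.51. Of 28 Raji B markers 1 rose and 1 fell, and 2 rose and 5 fell adjusted over the list alone (list adjusted p = 0.715; its median was -0.01 and its mean 0.02), CD24 at 1.27 and BCL11A at -0.24.

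**Figure D1:**
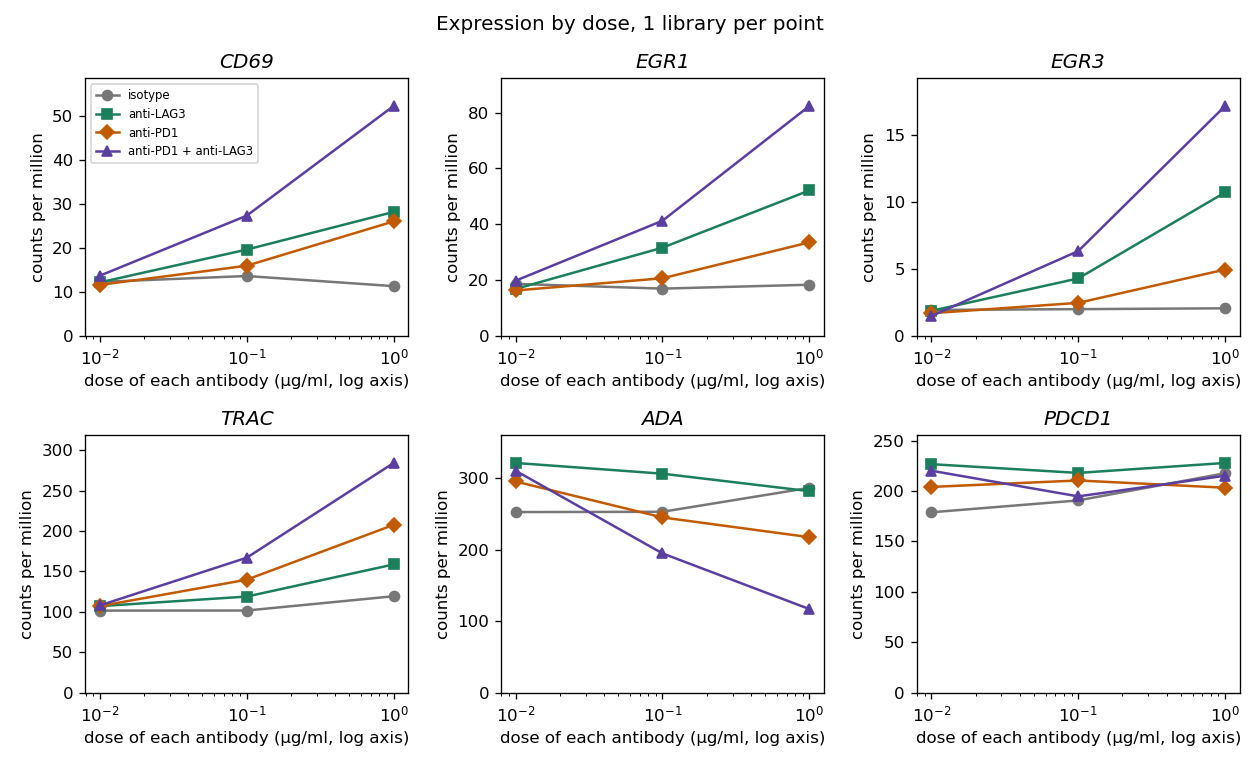
CPM of CD69, EGR1, EGR3, TRAC, ADA and PDCD1 against the dose of each antibody in µg/ml on a log axis, with 1 point per library and a line per arm. With the combination CD69 stood at 13.6 CPM at the lowest dose and 52.2 CPM at the highest, while the isotype libraries stayed between 11.2 and 13.5 CPM.

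With anti-LAG3 alone, CD69 and EGR1 also rose with dose. CD69 stood at 28.1, 19.5 and 12.1 CPM at 1, 0.1 and 0.01 µg/ml, and EGR1 at 52.1, 31.6 and 16.7 CPM. Against the isotype slope 11 genes changed, 9 upward and 2 downward, and with the T minus B marker difference as a covariate 33, 12 upward and 21 downward. EGR1 rose by 0.82 ± 0.08 log2 per 10-fold dose (adjusted p = 2.74e-06), CD69 by 0.66 ± 0.09 (adjusted p = 0.00111), EGR3 by 1.23 ± 0.19 (adjusted p = 0.00259) and IER3, an immediate early gene, by 0.71 ± 0.11 (adjusted p = 0.00259). CASC15, CRTAM, DUSP2, PRKCH, a protein kinase C, and TRBV12-3, a TCR beta variable segment, also rose, while MAZ and PPDPF fell. The TCR-induced early genes rose as a list, with 5 of 42 up, and 13 up and 2 down adjusted over the list alone (list adjusted p = 4.99e-04, and 0.461 with an estimated correlation). NF-kB target genes rose as a list with 0 members called (list adjusted p = 0.0480, and 0.461 with an estimated correlation). Mitochondrially encoded mRNAs fell as a list with 0 called, and 11 down adjusted over the list alone (list adjusted p = 3.55e-09, and 0.547 with an estimated correlation). Histone genes fell with 0 called (list adjusted p = 1.33e-05, and 0.546 with an estimated correlation), and Raji B markers with 0 called and 4 down adjusted over the list alone (list adjusted p = 0.00801, and 0.655 with an estimated correlation). The Raji B list pointed up without isotype at 1 µg/ml, and within the isotype series itself these markers rose with dose (list adjusted p = 3.12e-04, and 0.474 with an estimated correlation).

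The anti-LAG3 count was 1 without anti-LAG3 at 1 µg/ml and 1 without isotype at 1 µg/ml. Without anti-LAG3 at 0.01 µg/ml it was 10, with 3 up and 7 down, of which 2 were among the 11. Without isotype at 0.01 µg/ml it was 13, with 5 up and 8 down, of which 4 were among the 11. It was 17 without anti-LAG3 at 0.1 µg/ml, 21, 24 and 24 without anti-PD1 at 1, 0.1 and 0.01 µg/ml, and 17, 18 and 19 without the combination at those doses. Of these genes EGR1 passed in all 12 fits that left out 1 library, CD69 in 9 and EGR3 in 8.

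With anti-PD1 alone, CD69 stood at 26.0, 15.9 and 11.5 CPM and ADA at 217, 245 and 295 CPM. Against the isotype slope 41 genes changed, 13 upward and 28 downward. With slopes tested against 0 instead, 32 genes were called, most of them upward. CD69 rose by 0.66 ± 0.09 log2 per 10-fold dose (adjusted p = 0.00139), POLR2L, a small subunit of RNA polymerases, changed by -0.38 ± 0.05 (adjusted p = 0.00139), ADA by -0.31 ± 0.05 (adjusted p = 0.00139) and EGR1 by 0.55 ± 0.08 (adjusted p = 0.00174). PRKCH rose by 0.37 and UBASH3B, a phosphatase that dampens TCR signalling, by 0.35. Ribosomal proteins fell as a list, with 3 of 53 down, and 30 adjusted over the list alone (list adjusted p = 2.69e-13, and 0.646 with an estimated correlation), among them RPL28 by -0.27. Raji B markers fell with 0 called, and 7 down adjusted over the list alone (list adjusted p = 3.90e-04, and 0.646 with an estimated correlation). Ribosomal proteins and Raji B markers rose with dose within the isotype series itself, and that rise enters these falls with the opposite sign. Of the TCR-induced early genes CD69, EGR1 and IER3 rose, and 6 adjusted over the list alone, while EGR3 had a slope of 0.77 (adjusted p = 0.105) and the list had an adjusted p of 0.0681. The count was 0 without isotype at 1 µg/ml, 64 and 65 without isotype at 0.1 and 0.01 µg/ml, and 12, 122 and 6 without anti-PD1 at 1, 0.1 and 0.01 µg/ml. The direction turned to 9 up and 3 down without anti-PD1 at 1 µg/ml, where 3 of the 41 genes were called, and to 5 up and 1 down without it at 0.01 µg/ml. With the marker covariate 6 genes were called, 1 up and 5 down. The correction for GC content and length left 28 genes, 14 in each direction, of which 21 were among the 41.

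Whether the combination had a steeper dose response than each single antibody was tested on the slopes themselves. Against anti-PD1 100 slopes differed, 53 upward and 47 downward, and against anti-LAG3 119 differed, 50 upward and 69 downward. ADA fell further with the combination, by 0.48 ± 0.05 log2 per 10-fold dose against anti-PD1 (adjusted p = 2.34e-06) and 0.61 ± 0.05 against anti-LAG3 (adjusted p = 1.64e-08). CD69 rose further, by 0.37 ± 0.09 against anti-PD1 (adjusted p = 0.0481) and 0.36 ± 0.09 against anti-LAG3 (adjusted p = 0.0384). Against anti-PD1 EGR1 differed by 0.49, EGR2 by 1.02, EGR3 by 0.88 and LCP2, an adaptor of TCR signalling, by 0.59. Against anti-LAG3 TRAC differed by 0.41, and CD5 and CD6, surface receptors of T cells, by 0.46 and 0.34. The TCR-induced early genes differed upward in both: 8 of 42 against anti-PD1, and 18 adjusted over the list alone (list adjusted p = 1.94e-07, and 0.0655 with an estimated correlation). Against anti-LAG3 it was 4, and 11 up and 1 down adjusted over the list alone (list adjusted p = 7.03e-05, and 0.104 with an estimated correlation).

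MHC class I genes also had steeper slopes with the combination. Of 13 genes 4 differed upward against anti-PD1, and 9 adjusted over the list alone (list adjusted p = 7.03e-08, and 0.0655 with an estimated correlation). Against anti-LAG3 it was 2, and 8 adjusted over the list alone (list adjusted p = 7.03e-05, and 0.104 with an estimated correlation). A departure of the slopes from the sum of the single-antibody slopes was found for 0 genes by edgeR and 0 by DESeq2, with 1029 genes at an unadjusted p under 0.05 in edgeR. The 100 slopes against anti-PD1 were 6 without the combination at 1 µg/ml, 35 without it at 0.01 µg/ml, and 16 without anti-PD1 at 1 or at 0.01 µg/ml. The 119 against anti-LAG3 were 28 and 38 without the combination at 1 and 0.01 µg/ml, 19 and 8 without anti-LAG3 at 1 and 0.01 µg/ml, and 180 and 181 without anti-PD1 at 0.1 and 0.01 µg/ml. With the T minus B marker difference as a covariate they were 0 and 9.

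**Figure D2:**
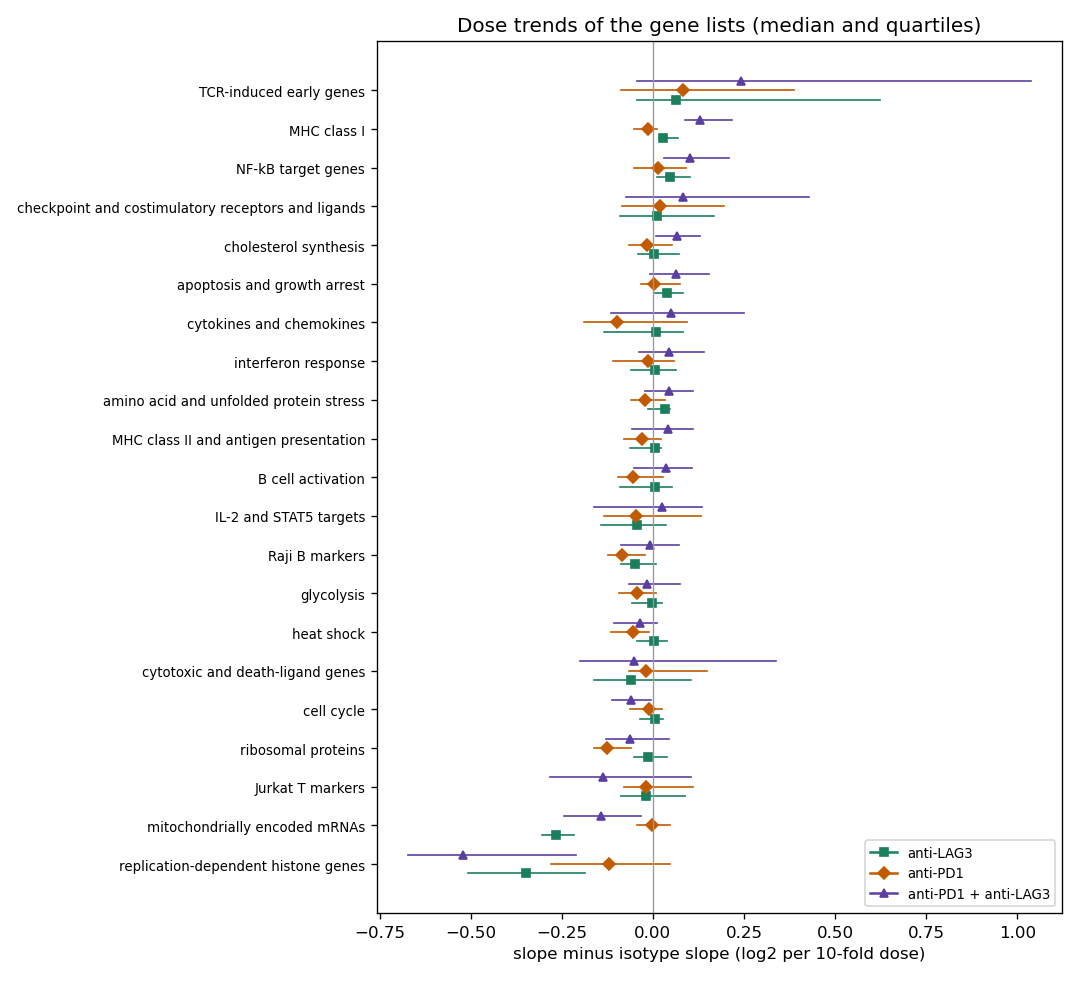
Median and quartiles of the slope in log2 per 10-fold dose, minus the isotype slope, for the tested members of each of 21 gene lists in the anti-LAG3, anti-PD1 and combination arms. The median of the early genes lies to the right of 0 with the combination, where 17 of 42 members rose.

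Most genes called in the slopes of a single antibody were also called with the combination. Of the 11 anti-LAG3 genes all were also called with the combination, 9 up and 2 down, where independent lists would share 0.165 and 0.0560. Of the 41 anti-PD1 genes 11 were also up and 27 also down with the combination, where independent lists would share 0.238 and 0.784. All arms were set against the same isotype libraries, so part of the excess may come from the shared controls. Across genes, which are not independent replicates, the slopes of anti-LAG3 and the combination had r = 0.54 and covariance 0.0444, against 0.48 and 0.0272 in simulations of unchanged arms. For anti-PD1 and the combination r was 0.55 and the covariance 0.0467, against 0.47 and 0.0273. The simulations held no bias shared by the genes of a library, so they do not size the part of the shared controls. Without any shared control, 664 genes had a slope other than 0 within the combination arm. Of these 73.2% had the same direction within the anti-LAG3 arm, where 54.4% of all genes did, 70.3% within the anti-PD1 arm, where 52.4% did, and 37.5% within the isotype arm, where 45.7% did. Within the arms CD69 had slopes of -0.06 in isotype, 0.60 in anti-LAG3, 0.60 in anti-PD1 and 0.97 in the combination.

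The second question was which genes differed between arms whatever the dose. In the anti-LAG3 arm MKI67, a marker of dividing cells (chromosome 10, 128096659 to 128126385, minus strand), was lower than with isotype, at 143, 121 and 178 CPM at 1, 0.1 and 0.01 µg/ml against 255, 302 and 301 CPM. TRAPPC5, a subunit of a vesicle tethering complex (chromosome 19, 7680843 to 7687703, plus strand), was higher, and so was STAT4, a transcription factor of cytokine signalling. Of 53 ribosomal protein genes 18 were higher, and of 13 mitochondrially encoded mRNAs 3 were lower. These differences were mostly small: the median size among called genes was 0.24 log2.

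The arms also differed as whole libraries. On the first principal component, with 33.5% of the variance, the 6 libraries with a single antibody lay at -8.39 to -1.93 and the 6 isotype and combination libraries at 2.48 to 8.14. The loadings of 9254 genes on it had r = -0.46 with GC content and 0.45 with log2 length, across genes, which are not independent replicates. Mitochondrially encoded mRNAs took 2.46% to 3.36% of the counts in the single-antibody libraries and 3.48% to 4.09% in the others. The departure from additivity had r = -0.52 with GC content and 0.39 with log2 length across 9185 genes. The second component, with 24.1% of the variance, set the combination at 1 µg/ml apart, at 13.9.

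**Figure D3:**
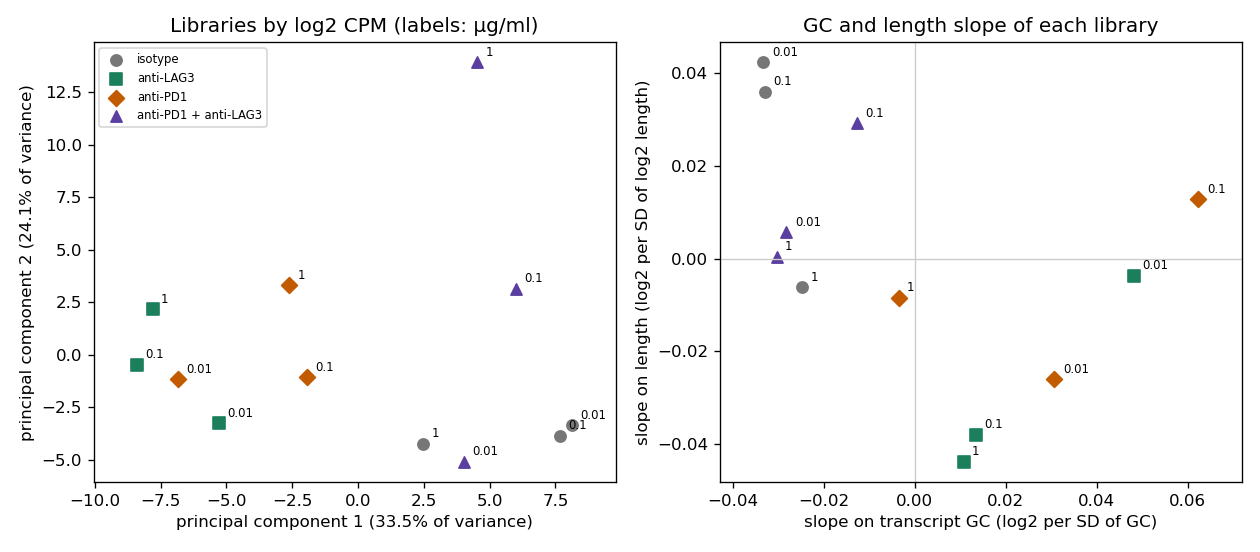
Left, first and second principal component of log2 CPM for the 12 libraries, coloured by arm; right, for each library the slope of its log2 ratio on GC content against that on log2 length, both per SD. The 6 single-antibody libraries lie at -8.39 to -1.93 on the first component and the other 6 at 2.48 to 8.14.

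Anti-LAG3 differed from isotype in 1560 genes, 758 higher and 802 lower. MKI67 fell by 0.95 ± 0.20 log2 (adjusted p = 0.0374), TRAPPC5 rose by 0.68 ± 0.09 (adjusted p = 4.67e-04) and STAT4 by 1.01 ± 0.29 (adjusted p = 0.0295). PILRB, a paired immunoglobulin-like receptor, fell by 1.10 ± 0.28 (adjusted p = 0.0165), NPIPB4, of a duplicated gene family, by 0.95 (adjusted p = 0.00224), and IKZF3, a lymphoid transcription factor, by 0.75 (adjusted p = 0.0340). Rises of 0.60 to 0.91 were seen in SPSB3, BHLHE23, AVPI1, EMID1, AKR1C3, TMEM35B, KAZALD1 and MDP1. With the T minus B marker difference as a covariate the count was 303, 209 higher and 94 lower, of which 256 were among the 1560, and with arm-specific dose slopes it was 2568. The count was 687 and 474 without anti-LAG3 at 1 and 0.1 µg/ml, and 424 and 764 without isotype at 0.1 and 0.01 µg/ml. After the correction for GC content and length 657 genes were called, 230 higher and 427 lower, of which 446 were among the 1560, with TRAPPC5 at 0.55 (adjusted p = 0.00262) and MKI67 at -0.84 (adjusted p = 0.0741).

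Ribosomal proteins were higher with anti-LAG3, with 18 of 53 up and 25 adjusted over the list alone (list adjusted p = 3.35e-09, and 0.560 with an estimated correlation), and mitochondrially encoded mRNAs lower, with 3 of 13 down and 10 adjusted over the list alone (list adjusted p = 1.81e-07, and 0.560 with an estimated correlation). MT-ND5 fell by 0.62 ± 0.11 (adjusted p = 0.0128). Cholesterol synthesis was higher, with 8 of 27 up and 11 adjusted over the list alone (list adjusted p = 0.00225, and 0.560 with an estimated correlation), such as FDPS by 0.25, and so was glycolysis, with 4 of 25 up and 8 adjusted over the list alone (list adjusted p = 0.00116, and 0.560 with an estimated correlation), such as PGAM1 by 0.19. Of 24 Jurkat T markers 5 were higher, also adjusted over the list alone (list adjusted p = 0.00116, and 0.560 with an estimated correlation), such as LCK, the kinase that starts TCR signalling, by 0.27. Of 28 Raji B markers 1 was higher and 5 lower, and 1 higher and 11 lower adjusted over the list alone (list adjusted p = 0.0374, and 0.560 with an estimated correlation), such as PAX5, a B lineage transcription factor, at -0.20. The T minus B marker difference, 0.195 above isotype in this arm, is computed from these same markers and is no separate evidence. Interferon response genes were higher, with 6 of 50 up and 1 down, and 7 up and 3 down adjusted over the list alone (list adjusted p = 0.0374, and 0.560 with an estimated correlation), where ISG15 rose by 0.36 (0.16 after the correction for GC content and length). MHC class I genes, with 4 of 13 up and 1 down, and 9 up and 2 down adjusted over the list alone (list adjusted p = 0.0118, and 0.560 with an estimated correlation), the TCR-induced early genes, with JUNB, a partner of FOS, up and 0 of 42 adjusted over the list alone (list adjusted p = 0.00225, and 0.560 with an estimated correlation), and the amino acid and unfolded protein stress list, with 4 of 30 up and 1 down, and 5 up and 1 down adjusted over the list alone (list adjusted p = 0.0460, and 0.560 with an estimated correlation), were higher. JUNB stood at 0.16, and at -0.03 after the correction for GC content and length.

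Anti-PD1 differed from isotype in 594 genes, 325 higher and 269 lower, again by a median of 0.24 log2. TRAPPC5 rose by 0.64 ± 0.10 log2 (adjusted p = 0.00389) and ENDOG, a mitochondrial nuclease, by 0.49 ± 0.08 (adjusted p = 0.00428). SPATA5 fell by 0.53 ± 0.09 (adjusted p = 0.00500) and ZNF121, a zinc finger gene, by 0.43 ± 0.07 (adjusted p = 0.00461). Glycolysis was higher, with 3 of 25 up and 6 adjusted over the list alone (list adjusted p = 3.09e-05, and 0.507 with an estimated correlation), and so was cholesterol synthesis, with 5 of 27 up and 9 adjusted over the list alone (list adjusted p = 1.40e-04, and 0.507 with an estimated correlation). Ribosomal proteins were higher, with 9 of 53 up and 16 adjusted over the list alone (list adjusted p = 1.58e-05, and 0.568 with an estimated correlation). Mitochondrially encoded mRNAs were lower with 0 called, and 4 adjusted over the list alone (list adjusted p = 1.58e-05, and 0.507 with an estimated correlation). Also higher were MHC class I genes, with 3 of 13 up and 8 adjusted over the list alone (list adjusted p = 0.00190, and 0.507 with an estimated correlation), and checkpoint genes, with 3 of 28 up, also adjusted over the list alone (list adjusted p = 0.0224, and 0.507 with an estimated correlation). The amino acid and unfolded protein stress list, with 5 of 30 up and 1 down (5 and 2 adjusted over the list alone), the TCR-induced early genes, with 1 of 42 up, and the interferon response, with 4 of 50 up and 5 adjusted over the list alone, had list adjusted p of 0.0106, 0.0172 and 0.0441, each with an adjusted p of 0.507 with an estimated correlation. Histone genes were lower with 0 called (list adjusted p = 0.0398, and 0.692 with an estimated correlation). After the correction for GC content and length 27 genes were called, 9 higher and 18 lower, of which 17 were among the 594. Of the 594 genes 572 had a smaller fold after it, with a median of 0.14 against 0.24 in the uncorrected direction, while their median standard error went from 0.0548 to 0.0509. ENDOG went from 0.49 to 0.29 (adjusted p = 0.125).

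The anti-PD1 count was 0 without anti-PD1 at 0.01 µg/ml or without isotype at 0.1 µg/ml. It was 201 without anti-PD1 at 0.1 µg/ml, where the majority turned, with 79 higher and 122 lower, and 335 without the combination at 0.1 µg/ml, and 1044 and 215 without isotype at 1 and 0.01 µg/ml. Anti-PD1 and anti-LAG3 shared 282 higher and 237 lower genes and none in opposite directions, where independent lists would share 15.9 and 13.9. Part of this excess may come from the shared controls: across genes r was 0.65 and the covariance 0.0448, against 0.48 and 0.0195 in simulations. The simulations drew each gene independently, without the GC and length bias of the libraries, so they do not size that part. Between anti-PD1 and anti-LAG3 0 genes differed by edgeR and 0 by DESeq2, with 691 at an unadjusted p under 0.05 in edgeR.

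The combination differed from isotype in 1 gene, SLC6A13, a transporter of GABA, by 3.08 ± 0.41 log2 (adjusted p = 0.00177), with 100, 32 and 7 counts at 1, 0.1 and 0.01 µg/ml against 10, 5 and 3. The same gene was the 1 called for anti-PD1 present against absent, at 1.86 log2, and for anti-LAG3 present against absent 0 genes were called by edgeR and 2 by DESeq2, with 836 at an unadjusted p under 0.05 in edgeR. For the combination against isotype DESeq2 called 18 genes, and edgeR 231 with arm-specific dose slopes, 316 with doses 1 and 0.1 µg/ml only and 145 with no filter on low counts, while 1037 had an unadjusted p under 0.05 in the main test. CD69 was 1.20 log2 higher than isotype in the mean of the doses (adjusted p = 0.574), since the model of arm means counts a dose response as spread. Several lists passed the test with 0 called members, and the 4 with the smallest p were higher. They were the TCR-induced early genes (list adjusted p = 1.61e-09), checkpoint and costimulatory genes (3.10e-07), interferon response (7.63e-07) and cytokines (1.34e-06), each with an adjusted p of 0.0920 with an estimated correlation. Adjusted over the list alone 8, 6, 5 and 5 of their members were higher. The count was 271 without the combination at 0.01 µg/ml, 58 without isotype at 0.01 µg/ml, 0 without the combination at 1 µg/ml, and 2 without anti-PD1 at 1 or 0.1 µg/ml or the combination at 0.1 µg/ml. For anti-PD1 present against absent it was 142 and 10 without the combination or isotype at 0.01 µg/ml and 0 without any other library.

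The combination differed from anti-LAG3 in 893 genes, 405 higher and 488 lower, and from anti-PD1 in 55, 18 higher and 37 lower. Ribosomal proteins were lower than with anti-LAG3, with 7 of 53 down and 20 adjusted over the list alone (list adjusted p = 1.42e-06, and 0.569 with an estimated correlation). Mitochondrially encoded mRNAs were higher, with 2 of 13 up and 7 adjusted over the list alone (list adjusted p = 1.42e-06, and 0.569 with an estimated correlation). NPIPB4 was 0.94 higher and PILRB 1.07 higher than with anti-LAG3, and TRAPPC5 changed by -0.52 and ENDOG by -0.49 against anti-PD1. After the correction for GC content and length 376 genes, 216 higher and 160 lower, and 1 gene were called. With the T minus B marker difference as a covariate it was 45 against anti-LAG3, 10 higher and 35 lower, and 122 against anti-PD1. With arm-specific dose slopes it was 1960 and 805, with doses 1 and 0.1 µg/ml only 1418 and 92, with only the arms compared 384 against anti-PD1, with no filter on low counts 349 and with DESeq2 160. Against anti-LAG3 the count was 160 and 135 without anti-LAG3 at 1 and 0.1 µg/ml, 477 and 47 without the combination at those doses, and 1487 and 561 without isotype at those doses. Against anti-PD1 it was 16, 14 and 0 without anti-PD1 at 1, 0.1 and 0.01 µg/ml, 104, 2 and 193 without the combination, 353, 11 and 106 without isotype, and 22 without anti-LAG3 at 1 µg/ml.

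The third question was whether the combination differed from the sum of the single-antibody effects. In 2372 genes the combination minus both single arms plus isotype was other than 0, 1134 upward and 1238 downward, with a median size of 0.35 log2. MKI67 had 1.49 ± 0.29 (adjusted p = 0.0186), PILRB 1.36, CENPE, a kinesin of cell division, 0.75 (adjusted p = 6.11e-05), TRAPPC5 -1.20 ± 0.14 (adjusted p = 1.65e-05) and ISG15 -0.62 (adjusted p = 2.64e-05). Ribosomal proteins were down, with 21 of 53 and 26 adjusted over the list alone (list adjusted p = 2.05e-07, and 0.773 with an estimated correlation), and mitochondrially encoded mRNAs up, with 5 of 13 and 10 adjusted over the list alone (list adjusted p = 3.24e-07, and 0.773 with an estimated correlation), as MT-ND5 at 0.99. Glycolysis was down, with 8 of 25, and 1 up and 10 down adjusted over the list alone (list adjusted p = 2.22e-04, and 0.773 with an estimated correlation). Cholesterol synthesis was down, with 2 of 27 up and 10 down, and 2 up and 11 down adjusted over the list alone (list adjusted p = 0.0240, and 0.773 with an estimated correlation). B cell activation was up, with 6 of 31, also adjusted over the list alone (list adjusted p = 0.0178, and 0.773 with an estimated correlation). Raji B markers were up, with 7 of 28 up and 1 down, and 10 up and 1 down adjusted over the list alone (list adjusted p = 0.0306, and 0.773 with an estimated correlation). MHC class I genes were down, with 2 of 13 up and 6 down, and 2 up and 8 down adjusted over the list alone (list adjusted p = 0.0447, and 0.864 with an estimated correlation). The count was 1434 without anti-PD1 at 0.01 µg/ml, 1506 without the combination at 0.1 µg/ml and 1455 without isotype at 0.1 µg/ml. After the correction for GC content and length it was 1049, 615 upward and 434 downward, of which 715 were among the 2372, 714 in the same direction. With the T minus B marker difference as a covariate it was 1098, 449 upward and 649 downward, of which 987 were among the 2372.

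The authors' comparison of each antibody library with the isotype libraries was set beside these values. For the combination the authors' deposited table had 164 genes up and 86 down at 1 µg/ml, 23 and 4 at 0.1 µg/ml, and 0 and 0 at 0.01 µg/ml, at an adjusted p under 0.05. With 0 genes at 0.01 µg/ml, 28 genes had an unadjusted p under 0.05 in the authors' deposited table. In the authors' deposited table CD69 had log2 fold changes of 2.09, 1.15 and 0.15 at the 3 doses of the combination, EGR1 2.21, 1.20 and 0.14, and ADA -1.17, -0.44 and 0.24. For anti-LAG3 the authors' deposited table had 86 up and 130 down at 1 µg/ml, 43 and 143 at 0.1 µg/ml, and 1 and 9 at 0.01 µg/ml, with CD69 at 1.19, 0.66 and -0.02. For anti-PD1 it had 27 up and 28 down at 1 µg/ml, 0 and 0 at 0.1 µg/ml, where 550 genes had an unadjusted p under 0.05, and 39 and 43 at 0.01 µg/ml, in the authors' deposited table. In the authors' deposited table an adjusted p was given for 8368, 6557 and 5117 genes of anti-LAG3 at 1, 0.1 and 0.01 µg/ml. For anti-PD1 it was given for 12421, 15005 and 5669, and for the combination for 14421, 13585 and 15082. The counts therefore come from unlike sets of genes, and CD69 and EGR1 had no adjusted p with anti-LAG3 at 0.1 µg/ml. Across genes, Spearman's rho between the fold changes in the authors' deposited table and the log2 ratio to the isotype library of the same dose was 0.730 to 0.881.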

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

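Of the tests in this part, the other splits of the libraries were fixed before their results were seen. The tests of GC content and length, of a departure that grows with dose, of library batch, of the Jurkat markers and of a deviating combination library were chosen after the results they bear on were seen. The test of a growing departure replaced one fixed beforehand on the 2372 called genes, whose ratio of 1.40 decides nothing, since the arm model selects against genes that differ by dose. Its range from unlike contrasts of the libraries was added after its value was known. The last of these tests replaced an earlier test of the early genes that had decided nothing, and its value was known when its bound was set.

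Results are listed here because a test of the difference between arms found it. The departure from additivity covered 2372 genes. The slope on dose differed between the combination and anti-PD1 in 100 genes and between the combination and anti-LAG3 in 119 genes. For these slopes 6 and 4 of 18 arrangements of the doses gave as many genes, so chance cannot be excluded for them.

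The 2372 genes are part of a pattern in which the anti-LAG3 and anti-PD1 libraries stood apart from the isotype and combination libraries in many genes by small amounts. Of 100 splits of the libraries, the real one and others drawn at random without regard to dose, only the real one gave as many genes. The highest of the others was 286, so a random grouping of the libraries is unlikely to give this count. GC content and length as the whole cause are argued against only weakly, since 1049 genes were called after both were corrected for. Genes without a GC value stayed uncorrected and may be among the 1049. GC content and length may account for part of the pattern: the median size of the 2372 went from 0.35 to 0.21, with 2116 smaller. For anti-PD1 against isotype 594 calls became 27, and the median fold of the 594 went from 0.24 to 0.14, with 572 smaller. An antibody effect that grows with dose stays open. Over all 15535 genes the departure at 0.01 µg/ml was 1.76 times that at 1 µg/ml (1.53 to 2.02 over resampled genes). Of 1451 genes chosen at the 2 higher doses, 1406 (96.9%) kept their direction at 0.01 µg/ml. Their median was 0.39 at 0.01 and 0.35 at 1 µg/ml. These values speak against growth, but each dose had 4 single libraries, and the spread between libraries is not covered by them. Unlike contrasts of the libraries covaried between doses by up to 0.0532, against 0.0576 and 0.102 behind the ratio. Taken as spread, this would put the ratio anywhere from 0.436 to 34.7. The contrasts share arms, however, so a lasting difference between arms also enters that range, which is not a measure of spread alone. A library batch stays open. All 12 libraries lay with their own arm on 1 side of the first component, single antibodies against isotype and combination. The labels give no batch, and a batch that follows the arms cannot be told apart from an antibody effect. The share of the 2 cell lines was not among these tests and also stays open for part of the pattern. The T minus B marker difference was 0.195 above isotype with anti-LAG3, 0.0426 with anti-PD1 and 0.0196 with the combination. With that difference as a covariate fewer genes departed from additivity, as given above.

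In the other pattern, CD69, EGR1, EGR3 and other genes of T cell receptor signalling rose with the dose of the combination. A larger share of Jurkat RNA at higher doses is argued against, since 6 of 24 Jurkat T markers fell with dose while 4 rose, and the T minus B marker difference had a slope of -0.0872 in the combination, although adding that difference to the model took the 719 genes to 119, ADA, EGR1 and CD69 among them. GC content and length are argued against, since 690 of the 719 genes, 96.0%, were called after correction. A single deviating combination library at 1 µg/ml is not settled by the gene count. Without it 190 of the 719 genes were called, but the same isotype slope was still taken off. Genes called through the isotype series would remain. Other arrangements of the doses gave up to 385 calls. ADA, EGR1, EGR3 and CD69 passed without that library. The earlier, undecided test had a median step of 0.20 in 42 early genes from 0.01 to 0.1 µg/ml in the combination minus isotype (quartiles -0.04 to 0.76, 29 positive). From 0.1 to 1 µg/ml its median step was 0.37 (31 positive). A response of the co-culture to both antibodies stays open as a hypothesis, with 1 library per condition and 34 genes called without isotype at 1 µg/ml. That isotype library was nearest in counts to the combination at 0.01 µg/ml, at a chi-square per degree of freedom of 3.06. To the other isotype libraries it stood at 8.93 and 10.8. This likeness across arms and doses enters the slopes of the combination against isotype.

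Comparisons of 3 libraries with 3 allow 10 splits, and trends of 2 arms 18 arrangements of the doses, too few for a share under 0.05. Chance can therefore be excluded for none of them. For anti-LAG3 against isotype the real count was 1560 and the highest other 0, for anti-PD1 594 and 0, for the combination 1 and 73, for the combination against anti-PD1 55 and 1, against anti-LAG3 893 and 0, and for anti-PD1 against anti-LAG3 0 and 0. As many genes as the real count were given by 1, 1, 3, 1, 1 and 10 of the 10 splits. For the trends of anti-LAG3, anti-PD1 and the combination the real counts were 11, 41 and 719 and the highest others 108, 140 and 385, with 4, 3 and 1 of the 18 arrangements as high. For the slope of the combination against anti-PD1 and against anti-LAG3 they were 100 and 119 and the highest others 461 and 416, with 6 and 4 arrangements as high. For anti-PD1 present against absent the real count was 1 and the highest other 968, with 7 of 100 splits as high, so chance cannot be excluded. For anti-LAG3 present against absent the real count was 0 and the highest other 721, and all 100 splits are as high whatever the data, as are all 10 for anti-PD1 against anti-LAG3, so these counts say nothing of chance. Splits and dose arrangements that called several times the real count point to a structure of the samples.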

How the results depend on the processing

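All alternatives were fixed before the data were examined except the correction for GC content and length and the slopes tested against 0, which were added after. Where a call or count changed with a setting below, the cause was not tested, unless the setting itself removed genes or libraries. Depth limited genes near 0, such as IL2 and IFNG. LAG3 was also near 0, but whether depth set its counts is not known. With 1 library per condition every left-out library leaves a dose of an arm empty, so its arm is assumed to vary like the others.

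Counts of genes with relative log expression, upper quartile scaling, DESeq2 and the other settings stayed within 1.5 times the main count except as follows. For anti-PD1 present against absent, 1 gene became 0 with relative log expression, upper quartile scaling, at least 5 CPM, the marker covariate, no robust option, DESeq2 and the GC and length correction. With no filter on low counts the combination gave 145 genes against isotype and 349 against anti-PD1, anti-PD1 present 64, anti-LAG3 present 53, the trends of anti-LAG3 and anti-PD1 71 and 196, the slope of the combination 170 against anti-PD1 and 207 against anti-LAG3, and the departure from additive slopes 14. With at least 5 CPM the combination against isotype gave 0 and the anti-LAG3 trend 7.

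With arm-specific dose slopes, arm means differed in 2568 genes for anti-LAG3, 1494 for anti-PD1, 231 for the combination against isotype, 805 and 1960 for the combination against anti-PD1 and anti-LAG3, 3 for anti-PD1 against anti-LAG3, and 142 and 70 for anti-PD1 and anti-LAG3 present. With doses 1 and 0.1 µg/ml only, anti-PD1 gave 161, the combination 316 against isotype, 92 against anti-PD1 and 1418 against anti-LAG3, anti-PD1 against anti-LAG3 3, anti-PD1 and anti-LAG3 present 241 and 69, and the departure from additivity 1452. With only the arms compared, anti-PD1 gave 392, the combination 0 against isotype and 384 against anti-PD1, anti-PD1 against anti-LAG3 6, and the anti-LAG3 trend 40. Without the robust option the combination gave 29 against isotype and 21 against anti-PD1, anti-LAG3 present 1, and the anti-PD1 trend 27. With DESeq2 the combination gave 18 against isotype and 160 against anti-PD1, anti-LAG3 present 2, the combination trend 290, and its slope 58 against anti-PD1 and 57 against anti-LAG3. Slopes tested against 0 gave 28 for anti-LAG3.

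With the T minus B marker difference as a covariate, anti-LAG3 gave 303 genes, the combination 19 against isotype, 122 against anti-PD1 and 45 against anti-LAG3, anti-LAG3 present 4, and the departure from additivity 1098. The trends of anti-LAG3, anti-PD1 and the combination gave 33, 6 and 119, and the slope of the combination 0 against anti-PD1 and 9 against anti-LAG3. After the GC and length correction anti-LAG3 gave 657, anti-PD1 27, the combination 1 against anti-PD1 and 376 against anti-LAG3, the departure from additivity 1049, the anti-LAG3 trend 19, and the departure from additive slopes 2. The split of directions of the anti-PD1 trend moved to 4 up and 54 down with DESeq2 and to 14 and 14 after the correction. With the marker covariate the departure from additivity had 449 up and 649 down.

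The majority direction of the called genes turned in the following fits, given as genes up and genes down. Anti-LAG3 had 758 and 802, and turned to 920 and 815 with no filter on low counts, 1378 and 1190 with arm-specific dose slopes, 650 and 617 with doses 1 and 0.1 µg/ml only, 209 and 94 with the marker covariate and 713 and 710 with DESeq2. It also turned without anti-LAG3 at 0.1 µg/ml (254 and 220), anti-PD1 at 1 µg/ml (821 and 632), the combination at 1 µg/ml (913 and 883) or 0.01 µg/ml (1026 and 967), and isotype at 1 µg/ml (1098 and 947) or 0.01 µg/ml (413 and 351). After the GC and length correction it kept its majority, with 230 and 427. Anti-PD1 had 325 and 269, and turned to 410 and 452 with no filter, 192 and 200 with only the arms compared, 79 and 122 without anti-PD1 at 0.1 µg/ml and 9 and 18 after the correction. The combination had 405 and 488 against anti-LAG3, and turned to 82 and 78 without anti-LAG3 at 1 µg/ml, 347 and 324 without it at 0.01 µg/ml and 216 and 160 after the correction. Against anti-PD1 it had 18 and 37, and 1 and 0 after the correction. Anti-PD1 present had 1 and 0, and turned to 111 and 130 with doses 1 and 0.1 µg/ml only and 58 and 84 without the combination at 0.01 µg/ml. The departure from additivity had 1134 and 1238, and 615 and 434 after the correction.

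The anti-LAG3 trend had 9 and 2, and turned to 29 and 42 with no filter, 12 and 21 with the marker covariate, 3 and 7 without anti-LAG3 at 0.01 µg/ml and 5 and 8 without isotype at 0.01 µg/ml. The anti-PD1 trend had 13 and 28, and turned to 9 and 3 without anti-PD1 at 1 µg/ml, 5 and 1 without it at 0.01 µg/ml and 31 and 1 with slopes tested against 0. The combination trend had 284 and 435, and turned to 62 and 57 with the marker covariate, 65 and 36 without the combination at 0.01 µg/ml and 19 and 15 without isotype at 1 µg/ml. Its slope against anti-LAG3 had 50 and 69, and turned to 6 and 3 with the marker covariate, 10 and 9 without anti-LAG3 at 1 µg/ml and 26 and 12 without the combination at 0.01 µg/ml. Its slope against anti-PD1 had 53 and 47, close to even, and turned in 12 fits. The widest of these were 75 and 95 with no filter, 42 and 50 with upper quartile scaling, 1 and 5 without the combination at 1 µg/ml and 37 and 42 with only the arms compared.

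Each dose was a block of 4 libraries in the arm models. With no replicate block, that is with dose left out, anti-LAG3 gave 1465 genes, anti-PD1 518, the combination 0 against isotype, 39 against anti-PD1 and 743 against anti-LAG3, anti-PD1 against anti-LAG3 0, anti-PD1 and anti-LAG3 present 0 each, and the departure from additivity 2249. Pairing by dose was weak: over 18 pairs of libraries of the same dose the correlation was -0.263 to 0.333, with a median of 0.145.

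Leaving out each library in turn gave 424 to 2045 genes for anti-LAG3, lowest without isotype at 0.1 µg/ml and highest without isotype at 1 µg/ml. It gave 0 to 1044 for anti-PD1, lowest without anti-PD1 at 0.01 µg/ml or isotype at 0.1 µg/ml and highest without isotype at 1 µg/ml, and 0 to 271 for the combination, lowest without it at 1 µg/ml and highest without it at 0.01 µg/ml. The combination gave 0 to 353 against anti-PD1 (without anti-PD1 at 0.01 and isotype at 1 µg/ml) and 47 to 1487 against anti-LAG3 (without the combination at 0.1 and isotype at 1 µg/ml). Anti-PD1 against anti-LAG3 gave 0 to 0. Anti-PD1 present gave 0 to 142 and anti-LAG3 present 0 to 37, both highest without the combination at 0.01 µg/ml. The departure from additivity gave 1434 to 2967 (without anti-PD1 at 0.01 and isotype at 1 µg/ml). The anti-LAG3 trend gave 1 to 24 (without anti-LAG3 or isotype at 1, and anti-PD1 at 0.1 or 0.01 µg/ml), the anti-PD1 trend 0 to 122 (without isotype at 1 and anti-PD1 at 0.1 µg/ml), and the combination trend 34 to 955 (without isotype at 1 and anti-PD1 at 0.01 µg/ml). The slope of the combination gave 6 to 147 against anti-PD1 (without the combination at 1 and anti-PD1 at 0.1 µg/ml) and 8 to 181 against anti-LAG3 (without anti-LAG3 and anti-PD1 at 0.01 µg/ml). The departure from additive slopes gave 0 to 5.

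Of the values of gene lists 1676 kept direction and side of the threshold, 617 lost the call and 13 reversed, of which 139 losses were with an estimated correlation and 123 in fry. For named genes the numbers were 15158, 2268 and 4, with 479 newly called, and 116 values had no adjusted p in DESeq2. The reversed list values, as signed -log10 of the adjusted p, were the following. With the marker covariate Raji B markers for anti-LAG3 went to 0.00719, mitochondrial mRNAs in the combination trend to 0.536 and in its slope against anti-PD1 to 6.51. Leaving out 1 library in turn, mitochondrial mRNAs ranged from -0.136 (without anti-LAG3 at 1 µg/ml) to 5.37 for anti-PD1 against anti-LAG3. In the slope of the combination against anti-LAG3 they ranged from -0.530 (without anti-LAG3 at 1 µg/ml; -0.0345 without the combination at 1 µg/ml) to 8.21, and in the departure from additive slopes from -0.463 (without anti-LAG3 at 1 µg/ml) to 7.07. They ranged from -3.01 to 0.0733 in the combination trend and from -3.92 to 0.186 in its slope against anti-PD1, and Jurkat T markers from -2.30 to 0.0411 and from -3.20 to 0.145, in each case reversed without the combination at 0.01 µg/ml. Raji B markers ranged from -3.50 to 0.0775 in the anti-LAG3 trend and ribosomal proteins from -2.73 to 0.186 in the combination trend, both reversed without isotype at 1 µg/ml. Of genes, the GC and length correction reversed JUNB, from 0.16 to -0.029 for anti-LAG3 and from -0.27 to 0.066 for the departure from additivity, and LTB, from 0.18 to -0.013 and from -0.23 to 0.094.

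Of the main genes of the combination trend, ADA, EGR1, EGR3 and CD69 passed in each of the 12 fits that left out 1 library. In the anti-LAG3 trend EGR1 passed in 12 and CD69 in 9, with an adjusted p of 1.00 for CD69 without isotype at 1 µg/ml. In the anti-PD1 trend CD69 and ADA passed in 10, with an adjusted p of 1.00 for both without isotype at 1 µg/ml. EGR1 passed in 9, with its highest adjusted p of 0.254 without anti-PD1 at 1 µg/ml.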

Other observations

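The tests of LAG3 counts in this part were all chosen after the counts were seen, and the bound of the test on early genes was set with its value known.

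Among the genes that fell with the dose of the combination was DNTT, the terminal transferase of V(D)J recombination. It stood at 4.03, 6.88 and 14.6 CPM at 1, 0.1 and 0.01 µg/ml against 12.0, 13.8 and 12.6 CPM with isotype, and RAG2, of the V(D)J recombinase, at 1.88, 3.14 and 6.71 CPM against 5.98, 5.33 and 5.86 CPM. Their slopes against isotype were -0.91 ± 0.12 log2 per 10-fold dose for DNTT (adjusted p = 2.50e-05) and -0.96 for RAG2 (adjusted p = 3.35e-04). CD1E, a lipid-presenting molecule, had -0.42 and THEMIS, a regulator of TCR signalling, -0.45 (adjusted p = 4.59e-05). These genes were picked after their values were seen and were not tested as a list. TCF7, GATA3 and TAL1, transcription factors of the T lineage or of T cell leukaemia, had slopes of 0.07, 0.07 and -0.07 that did not pass the test (adjusted p = 0.577, 0.692 and 0.511).

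The isotype series had a dose trend of its own, tested against 0, in 133 genes, 115 upward and 18 downward. Between the counts of its libraries at 0.1 and 0.01 µg/ml the chi-square per degree of freedom was 1.76, the lowest of all pairs. The library at 1 µg/ml stood apart from these, at 8.93 and 10.8. It was nearest to the combination at 0.01 µg/ml, at 3.06. The isotype libraries at 0.1 and 0.01 µg/ml were near the combination at 0.1 µg/ml, at 3.23 and 3.36. Likeness of libraries therefore crossed arms and did not follow dose. The trend may therefore reflect that 1 library rather than dose. Such likeness also enters the slopes of the combination against isotype. PPDPF rose by 0.32 log2 per 10-fold dose (adjusted p = 2.23e-04) and RPL37, a ribosomal protein, by 0.29. Ribosomal proteins rose as a list, with 9 of 53 up, and 30 up and 1 down adjusted over the list alone (list adjusted p = 3.59e-09, and 0.535 with an estimated correlation). Raji B markers rose, with 2 of 28 up and 8 adjusted over the list alone (list adjusted p = 3.12e-04, and 0.474 with an estimated correlation). This slope enters every trend against isotype with the opposite sign, so the falls of ribosomal proteins and of Raji B markers with anti-PD1 hold it in part.

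LAG3 was counted at 0 to 2 reads in each of 12 libraries of a co-culture whose T cells are described as carrying it. Reads lost to an overlapping gene are argued against, since 0% of the 3056 exon bases of LAG3 are shared with exons of other genes. An absence of LAG3 for the antibody to act on is argued against only weakly: 5 of the TCR-induced early genes rose with the dose of anti-LAG3, a test set after that value was known, which replaced an undecided 1, the 11 trend genes of anti-LAG3, as 4 of 18 dose arrangements gave as many. An introduced LAG3 sequence that differs from the reference gene, such as a codon-changed construct whose reads would not be counted, could leave the highest count at 2 and stays open, since the reads were not analysed here.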
